A study of Mus musculus with 12 samples.

How the data were processed

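Gene expression was measured in primary bone marrow stroma, the adherent support layer that grows out of marrow in culture, from wild-type mice and from mice with 1 inactive copy of Crebbp or of Ep300. Both genes encode histone acetyltransferases that act as transcriptional coactivators. Per the labels, the mice were C57BL/6 and 3 to 4 months old, the marrow was plated for 2 weeks, the stroma layer was irradiated with 1500 cGy and given fresh medium, and biotin-labelled RNA was hybridized to Affymetrix arrays. There were 4 arrays per genotype, named as separate biological replicates in the labels, 12 in all. No batch or scan date is given in the sources used here.

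The authors deposited log2 expression values made with GCRMA, per the submitters' processing notes. GCRMA corrects background from probe sequence, normalizes between arrays and summarizes the probes of a probe set, so the values are relative levels and cannot be compared between probe sets. Its version and the chip definition are not given in the sources used here. The table held 3127 probe sets, of which 18 were control probe sets, and the other 3109 were tested. Each had an interquartile range of at least 0.5001 over the 12 arrays and at least 3 arrays at or above the log2 of 100, so the table is a part of the chip chosen on overall variability and level. That filter was read from the values and is not described in the sources used here. It removes flat genes without regard to genotype, so adjusted p-values and gene list tests compare variable probe sets with each other, and a gene absent from the table has no value here.

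Of the probe sets tested, 2486 had 1 gene symbol in the platform annotation, 176 had several and 447 had none, and no gene was named from the last 2 kinds. The single symbols covered 1974 genes. Of those probe sets, 2482 were matched by gene ID to the mouse gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names and for which genes share a chromosome, and no coordinates are given.

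No further normalization was applied. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit over all 12 arrays with a mean per genotype and no covariate. Tests were two-sided with Benjamini-Hochberg adjustment over the probe sets, and a probe set was called at an adjusted p under 0.05. Fold changes are differences of log2 means, given with limma's standard error (SE). The number of arrays limits the precision. On simulated data with the real means and residual spreads, for Crebbp+/- against wild type over 3109 probe sets, 80% of changes of 2 log2 units and 23% of changes of 1 log2 unit were called, with 7 false calls among 110. For Ep300+/- against wild type, simulated without change, 0 were called.

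The 24 gene lists (pathways and cell type markers) were fixed before the data were examined and were tested with limma's camera at its preset inter-gene correlation of 0.01, on the probe set of highest mean for each gene, with adjustment over the lists of a contrast. Camera compares a list with the other probe sets, while fry tests whether its members moved, on balance, one way and makes no such comparison. Lists with fewer than 5 measured members were only counted. On simulated data a planted shift of 1 log2 unit in the interferon list was called and 0 of the 15 other lists were. The simulated genes were independent, while the real interferon members had an estimated correlation of 0.724. The simulation thus cannot tell how often camera calls a list of correlated members falsely. The rule for named genes, fixed at the same time, took Crebbp and Ep300, then the 12 highest and 12 lowest fold changes among called genes with 1 symbol (6 and 6 between the heterozygotes), each gene taken by its probe set of highest mean, then, where fewer than 10 genes passed, those of smallest p up to 10, and up to 4 members of smallest p from each list with a call. Genes chosen after their values were seen are named as such.

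Replicate numbers recur in the 3 genotypes, and the labels do not say what they share. Deviations from the group means correlated between same-numbered arrays with r from 0.448 to 0.603 for Crebbp+/- and wild type, and from 0.294 to 0.513 for Crebbp+/- and Ep300+/-. With every pair above 0.1, the numbers were taken to pair the arrays of those comparisons, and results with the number as a block stand beside the counts they move by over 1.5 times. The preferred fit had been fixed without the block. Exact permutation tests treated the arrays as unpaired. Regrouping within pairs alone allows fewer regroupings, so the smallest possible p would be larger.

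Alternatives fixed in advance were quantile normalization, median centring, a filter on low values, eBayes with trend and robust, a fit of 2 genotypes at a time, array weights, the replicate block, a fold minimum of 1.5, leaving out each array, and for lists an estimated correlation, fry and the mean of a gene's probe sets. A spike-in covariate, a Y-linked transcript covariate, leaving out Crebbp+/- 3 with Ep300+/- 3, and the block with an estimated correlation were added after the data were seen. Tests of explanations for the NF-kB list had been drafted and were set aside unrun when a chromosome 1 pattern, seen later, took their place.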

Results

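Expression was profiled on 12 arrays of irradiated primary bone marrow stroma, with 4 from wild-type, 4 from Crebbp+/- and 4 from Ep300+/- mice. The array medians over the 3109 probe sets lay between 7.98 and 8.43 on the log2 scale. Correlations between arrays across probe sets, which are not independent replicates, were at most 0.964, so no array was a copy of another. The comparisons ask how loss of 1 copy of either coactivator changed the stroma, and whether the heterozygotes differed.

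Crebbp, the targeted gene, was measured by 1 probe set. Its log2 level was 8.52 ± 0.058 in wild-type stroma (mean ± SD, n = 4), 7.74 ± 0.091 in Crebbp+/- and 8.65 ± 0.12 in Ep300+/-. Crebbp+/- stroma thus held 58.4% of the wild-type level, lower in 4 of 4 arrays (log2 fold change -0.78, SE 0.20, limma adjusted p = 0.0372). An exact two-sided permutation test over the arrays gave p = 0.0286, the smallest that 4 against 4 unpaired arrays allow. In Ep300+/- stroma the log2 fold change of Crebbp was 0.13 (limma adjusted p = 0.965). Against Ep300+/- stroma Crebbp was lower in 4 of 4 arrays (log2 fold change -0.91, limma adjusted p = 0.0228). The limma call against wild type was lost without wild-type 1, 2, 3 or 4 (adjusted p = 0.0705, 0.0905, 0.0836 and 0.129), without Crebbp+/- 1, 2 or 3 (0.110, 0.103 and 0.0837), without Ep300+/- 1 or 2 (0.0616 and 0.0620), and without Crebbp+/- 3 and Ep300+/- 3 together (0.0522). It was also lost in a fit of these 2 genotypes alone (0.0607) and with a spike-in or Y-linked covariate (0.0532 and 0.180), while the log2 fold change without any 1 array stayed between -0.82 and -0.75. The call against Ep300+/- was lost without Crebbp+/- 1 or 2 (0.0766 and 0.0732) and without Ep300+/- 1, 2 or 4 (0.0729, 0.0511 and 0.0613), in a fit of these 2 genotypes alone (0.0918) and with the Y-linked covariate (0.146). The position of the probe set relative to the targeted part of the gene is not known here. Ep300 has no probe set among those analysed here, so the Ep300+/- labels have no such check.

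In Crebbp+/- against wild-type stroma, 192 probe sets passed, 156 higher and 36 lower, and 831 had an unadjusted p under 0.05. With the arrays taken as pairs, only 8 ways of regrouping them part every pair, too few to exclude chance. Ccl8, a monocyte chemokine, was higher (log2 fold change 4.81, SE 1.09, n = 4 per group, limma adjusted p = 0.0261). Wild-type 2, 3 and 4 lay between 3.66 and 3.68, low values that may be background, and wild-type 1 at 6.42, so the size of the Ccl8 change is uncertain. It was 5.50 without wild-type 1 and 5.41 without Crebbp+/- 4. Comp, a cartilage matrix protein, was 6.54-fold lower (log2 fold change -2.71, SE 0.30, limma adjusted p = 0.00155), and S100b, a calcium-binding protein, was 3.28-fold lower (log2 fold change -1.71, SE 0.22, limma adjusted p = 0.00375).

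Of the interferon response list, 17 of 21 genes were measured, and 13 rose, 0 fell and 4 did not pass the test. With adjustment over the list alone, 15 passed. Irf7, the interferon regulatory factor that drives type I interferon expression, rose by a log2 fold change of 2.27 (SE 0.37, limma adjusted p = 0.0128). Usp18, which removes the ubiquitin-like modifier ISG15, rose by 2.02 (SE 0.35, limma adjusted p = 0.0129), and the interferon-induced Ifit3 and Xaf1 rose by 1.84 and 1.47. The list median was 1.47, and camera gave an adjusted p of 1.81e-09, with an adjusted p = 0.538 with an estimated correlation and an adjusted p = 0.00859 by fry. All 4 Crebbp+/- list means lay above all 4 wild-type means (exact permutation p = 0.0286, the smallest possible for unpaired arrays). Oasl1 and Ifi213, 2 further interferon-induced genes outside the list, were higher by log2 fold changes of 2.95 and 3.08. Oasl1 lay between 4.12 and 4.67 in wild type, low values that may be background, so the size of its change is uncertain.

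Of the endothelial markers, 11 of 14 were measured, and 7 rose, 0 fell and 4 did not pass the test, while 11 passed with adjustment over the list alone. The adhesion molecules Pecam1 and Cdh5 rose by log2 fold changes of 1.98 (SE 0.40, limma adjusted p = 0.0184) and 2.09 (SE 0.43, limma adjusted p = 0.0184), and the surface proteins Emcn and Esam rose by 1.44 and 1.83. The list median was 1.83 and camera gave an adjusted p of 1.29e-06, with an adjusted p = 0.538 with an estimated correlation and an adjusted p = 0.0142 by fry. Crebbp+/- 4 stood apart, with a list mean of 0.047 against 1.503 to 1.87 on the other 3 Crebbp+/- arrays, and wild-type 1 reached 0.33. The exact permutation p of the list means was 0.0571. With the replicate number as a block all 11 passed over all probe sets. Among the 12 highest genes were also the list member Tie1, a receptor, at a log2 fold change of 2.32, the endothelial transcription factor Erg at 2.53, Adgrl4 (4.84-fold) and the pericyte-associated Rgs5 (5.95-fold). The other 3 probe sets of Rgs5 had log2 fold changes from 3.59 to 4.21, and Erg, with a size as uncertain as that of Oasl1 (wild type down to 3.71), had 3.15 without Crebbp+/- 4.

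Of the sterol and fatty acid synthesis list, 10 of 21 genes were measured, none passed singly over all probe sets, and 7 passed with adjustment over the list alone. Every one of the 10 fold changes was negative, with a median of -0.71, among them Lss (-0.94, SE 0.26, limma adjusted p = 0.0504), Cyp51 (-0.96), Idi1 (-0.83) and Sqle (-0.82), all enzymes of cholesterol synthesis. The list mean was -0.025 on Crebbp+/- 4, level with wild-type 3 (-0.024), against -0.73 to -0.61 on the other 3 Crebbp+/- arrays. Camera gave an adjusted p of 3.57e-06, with an adjusted p = 0.538 with an estimated correlation and an adjusted p = 0.0245 by fry. With the replicate number as a block, 7 of the 10 passed over all probe sets.

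Among the other genes lowest in Crebbp+/- stroma, Ibsp, a bone matrix sialoprotein, fell by 1.75 on the log2 scale (SE 0.42, limma adjusted p = 0.0293), and Igfbp6, an insulin-like growth factor binding protein, fell by 2.43. The water channel Aqp1, Lrrn4cl and Anxa8 were 3.95-fold, 6.46-fold and 3.65-fold lower. The cell adhesion molecule Cadm1 (-2.23), the collagen-binding integrin subunit Itga10 (-1.93), the matrix protein Smoc2 (-1.85), Clec11a (-1.56) and Hoxc8 (-1.36) were lower on the log2 scale. Of 3 measured osteoblast markers Ibsp passed, with Alpl at -1.03 and Pth1r at -0.66, and 2 passed with the replicate number as a block. The other 5 of the 12 highest genes were Ms4a4c, at 6.25-fold, and by log2 fold change Gimap4 (2.86), Ms4a8a (2.80), Upp1 (2.28) and Igkv8-30 (2.69), an immunoglobulin kappa segment. For Cadm1, Itga10, Smoc2, Clec11a, Hoxc8, Gimap4, Ms4a8a, Upp1 and Igkv8-30 the lower group had arrays under 5, a bound chosen after the values were seen. Such values may be background, so the size of these changes is uncertain. Without Crebbp+/- 4 the log2 fold change of Gimap4 was 3.45 and that of Ms4a8a 3.48, and without wild-type 1 that of Gimap4 was 3.53. Ranking each gene by its probe set of highest mean left out Btg2 and Gm2115, named after their values were seen, each with a probe set of lower mean that passed, at 4.97 (limma adjusted p = 0.0128, wild type down to 4.27) and -1.70.

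Elsewhere single members passed, with each gene taken by its probe set of highest mean. A probe set of lower mean also passed for the niche factor Jag1 (1.10, limma adjusted p = 0.0383) and for the adhesion gene Alcam (-1.32, limma adjusted p = 0.0275). Angptl4 (1.14) was the 1 of 12 measured niche factors, Ccl8 the 1 of 11 myeloid growth factors and chemokines, and Mcam (1.64) the 1 of 10 adhesion genes. Cd163 (1.18) was the 1 of 7 macrophage markers and Cd36 (-0.97) the 1 of 9 adipocyte markers. With the replicate number as a block the counts were 1, 2, 4, 2 and 2 in that order. These lists did not pass camera, with adjusted p-values of 0.526, 0.0968, 0.925, 0.248 and 0.248 in that order. The adhesion list had a positive median (0.31) and a downward camera direction, as did the matrix list (median 0.031). By the probe set of highest mean, no member passed in the lists of extracellular matrix (camera adjusted p = 0.906), matrix proteases (0.599), p53 targets (0.106), cAMP and CREB targets (0.786), NF-kB targets (0.248), TGF-beta and BMP targets (0.786), Wnt pathway (0.786) and Notch pathway (0.0723). A probe set of lower mean passed for the p53 target Btg2 (4.97, limma adjusted p = 0.0128) and, as above, for Jag1, also a Notch list member. The cell cycle, hypoxia, acetyltransferase, osteoclast, granulocyte, erythroid and lymphoid, and smooth muscle lists had 2, 3, 1, 4, 1, 1 and 4 measured members, of which 0 passed. With the block 4 members passed in the matrix list (2 higher, 2 lower), 2 each in the protease, p53, TGF-beta and smooth muscle lists, 3 in the Notch list, and 1 each in the cAMP, NF-kB, osteoclast and erythroid and lymphoid lists, while no further list passed camera.

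The number of calls rested on single arrays. Without wild-type 2, 3 or 4 it was 30, 48 or 5, without Crebbp+/- 1, 2, 3 or 4 it was 9, 7, 55 or 383, and without Ep300+/- 1 it was 125, and 5 of the 192 remained in every such fit. Of the 24 genes of largest change and Crebbp, 22, 5, 11 and 2 stayed past the threshold without wild-type 1, 2, 3 and 4, 4, 3, 10 and 25 without Crebbp+/- 1, 2, 3 and 4, and 17, 19, 25 and 25 without Ep300+/- 1, 2, 3 and 4. Comp and S100b passed in each of these 12 fits. With the replicate number as a block, 812 probe sets passed (544 higher, 268 lower), among them all 192. The Y-linked transcript Eif2s3y stood at 2.73 and 2.69 on Crebbp+/- 1 and 3 and between 8.41 and 10.84 on the other arrays, and with this as a covariate 3 probe sets passed. The median over all probe sets was 0.24 higher in Crebbp+/- than in wild type. Quantile normalization brought that to 0.022 and gave 120 higher and 72 lower, with 149 calls shared, and median centring brought it to 0.044 and gave 125 higher and 72 lower.

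**Figure D1:**
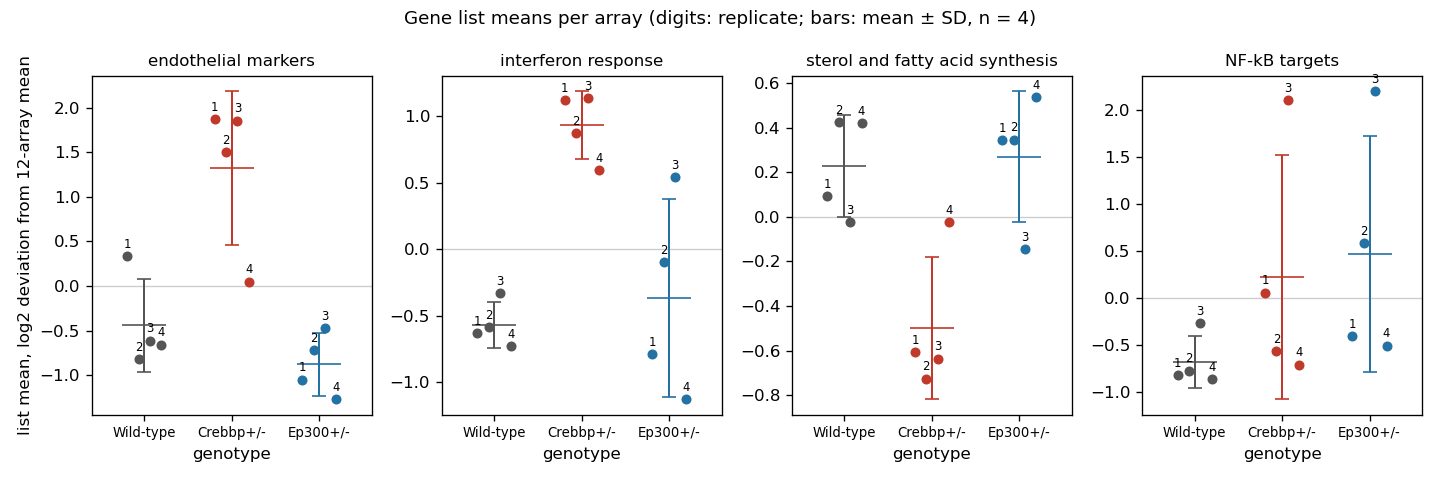
Mean log2 deviation of the members of 4 gene lists from their 12-array mean (vertical axis), for each array of the 3 genotypes (horizontal axis), with digits for the replicate and bars for the mean ± SD (n = 4). The interferon means of Crebbp+/- lie between 0.60 and 1.14, above all wild-type means, Crebbp+/- 4 has an endothelial mean of 0.047, and the NF-kB means of Crebbp+/- 3 and Ep300+/- 3 are 2.10 and 2.20.

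In Ep300+/- against wild-type stroma, no gene passed. By limma 0 probe sets had an adjusted p under 0.05, and 126 of 3109 had an unadjusted p under 0.05. The smallest p-values with 1 probe set per gene belonged to Stk25, a serine/threonine kinase, at 3.34-fold higher (log2 fold change 1.74, SE 0.28, limma adjusted p = 0.120), and to Tspan32, a haematopoietic tetraspanin, at 2.30-fold lower (-1.20, SE 0.23, limma adjusted p = 0.166). Next by p were Slc16a9 (-1.19), the aspartic protease Ctse (-1.28), Rnf144b (-1.001), Ankrd66 (-1.19), Aldh1a7 (1.08), Cgnl1 (-0.85), Gatm (1.0003) and Gsta3 (-0.83), with limma adjusted p-values from 0.309 to 0.632. The second probe set of Ctse had a log2 fold change of -0.0011.

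By list, camera called 6 of 16 without a single member past the test. Myeloid growth factors and chemokines (11 measured, median 1.498, adjusted p = 2.42e-05) and NF-kB targets (13 measured, median 1.14, adjusted p = 2.42e-05) were higher, each with an adjusted p = 0.628 with an estimated correlation. Among their members were Tnf at 2.86, Il1b at 3.88, Cxcl2 at 2.05, Ccl2 at 1.43, Irf1 at 1.88, Tnfaip3 at 2.17 and Nfkbia at 1.05. The cAMP and CREB immediate targets were also higher (11 measured, median 1.08, adjusted p = 0.00125, and 0.628 with an estimated correlation), with Pde4b at 1.97, Nr4a1 at 1.52, Atf3 at 1.25 and Junb at 1.08. Without Ep300+/- 3, Tnf was 1.84, Il1b 2.39, Cxcl2 1.29, Ccl2 0.74, Irf1 1.16, Tnfaip3 1.30 and Nr4a1 0.89, and the myeloid and cAMP medians were 0.74 and 0.49. Without Ep300+/- 4, Tnf was 3.56, Il1b 4.98, Cxcl2 2.75 and Ccl2 2.22, with a myeloid median of 2.501, and without Ep300+/- 1 Tnf was 3.48 and Il1b 4.71. In Crebbp+/- against wild type the myeloid list had a like median without a camera call (1.504, 11 of 11 positive, camera adjusted p = 0.0968). Its array means there gave an exact permutation p of 0.0286, the smallest possible for unpaired arrays, against 0.114 in Ep300+/-. The mean of Crebbp+/- 3 was 2.62, against -0.79 to 0.54 on the other Crebbp+/- arrays. Endothelial markers (median -0.43, adjusted p = 0.00715, Plvap -0.62, Cldn5 -0.93, Robo4 -0.61, Egfl7 -0.42), extracellular matrix (12 measured, median -0.25, adjusted p = 0.0245, Vcan -0.85, Col1a2 -1.05, Col3a1 -0.47, Tnc -0.37) and the Wnt pathway (5 measured, median -0.55, adjusted p = 0.0464, Dkk3 -0.56, Rspo3 -0.55, Sfrp1 -0.63, Fzd4 -0.13) were lower. With an estimated correlation these 3 gave 0.783, 0.628 and 0.628, and fry gave 0.767 for the endothelial list and 0.654 for the other 5, so no call held. Cldn5 was -0.27 without wild-type 1 and Col1a2 -0.45 without Ep300+/- 3. The NF-kB mean was 2.20 on Ep300+/- 3 and between -0.51 and 0.58 on the other Ep300+/- arrays, and Tnf stood at 14.36 on Ep300+/- 3, 12.29 on Ep300+/- 2 and 14.38 on Crebbp+/- 3, against 7.76 to 9.03 in wild type.

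Single arrays ended some of these calls. The cAMP list gave adjusted p-values of 0.0617 and 0.0810 without wild-type 1 and Ep300+/- 3, and the endothelial list 0.185 and 0.0721 without wild-type 1 and Ep300+/- 1. The matrix list gave 0.0522, 0.0752 and 0.0810 without wild-type 1, wild-type 3 and Ep300+/- 3, and the Wnt list 0.153, 0.114, 0.0545 and 0.329 without wild-type 1, wild-type 3, Crebbp+/- 2 and Ep300+/- 4. For the other 10 lists tested in Ep300+/- the camera adjusted p was 0.477 (niche factors), 0.389 (matrix proteases), 0.458 (interferon response), 0.490 (p53 targets), 0.711 (TGF-beta and BMP targets), 0.711 (Notch pathway), 0.711 (sterol and fatty acid synthesis), 0.711 (adhesion), 0.477 (adipocyte) and 0.389 (macrophage).

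The heterozygotes were also tested directly against each other, a comparison in which chance is not excluded either. With the arrays taken as unpaired, 2 of 35 ways of regrouping them gave as many calls as the real 199. With the arrays taken as pairs, only 8 ways part every pair, too few to exclude chance, though the highest other of these gave 0. All 11 measured endothelial markers rose in Crebbp+/- relative to Ep300+/- (median log2 fold change 2.14, camera adjusted p = 3.16e-09, and 0.495 with an estimated correlation). Cldn5, a tight junction protein, was higher (log2 fold change 3.40, SE 0.77, n = 4 per group, limma adjusted p = 0.0249), as were Icam2 and Tie1, by 2.92 each. Without Crebbp+/- 4 the log2 fold change of Cldn5 was 4.15. Of the interferon list 9 of 17 rose (median 1.25, camera adjusted p = 6.62e-09, and 0.495 with an estimated correlation), and Ifi213, Gimap4 and Igkv8-30 were higher by 3.47, 3.31 and 2.80. Ifi213 had 2.87 without Ep300+/- 1 (limma adjusted p = 0.0547) and 4.20 without Ep300+/- 3, and Gimap4 had 3.91 without Crebbp+/- 4. Of the sterol list 2 of 10, Idi1 (-1.04) and Lss (-0.98), fell and 8 did not pass (median -0.77, camera adjusted p = 2.04e-06, and 0.495 with an estimated correlation). Among these 8, Cyp51 had a probe set of lower mean that passed (-1.45, limma adjusted p = 0.0317). With the replicate number as a block, 14 of the interferon and 8 of the sterol genes passed. In other lists the block gave 4 niche factors, 4 matrix genes, 4 adhesion genes (1 of them lower), 3 Notch, 2 p53, 2 TGF-beta and 2 Wnt members. It gave 1 each in the myeloid, cell cycle, hypoxia, macrophage, osteoblast, osteoclast, smooth muscle, and erythroid and lymphoid lists. Of these single members, those of the cell cycle and osteoblast lists were lower. The skeletal muscle myosin Myh1 was lower (log2 fold change -4.10, SE 1.01, limma adjusted p = 0.0317), at -4.83 without Crebbp+/- 2 and -3.51 without Crebbp+/- 3 (limma adjusted p = 0.0475 and 0.0723). Comp, Igfbp6 and Lrrn4cl were 5.46-fold, 4.90-fold and 3.90-fold lower, and Cadm1 (-2.99) and Itga10 (-2.02) were lower on the log2 scale. Myh1 had values that may be background on Crebbp+/- 1 and 3 (2.80 and 2.36). Arrays of the lower group also lay under 5 for Cadm1, Itga10 and all 6 genes of largest increase, with lowest values from 3.28 (Icam2) to 4.41 (Itga10), so the size of all these changes is uncertain. Without the block Mcam (1.56), Itgb3 (1.99) and Myh11 (1.12) rose and Ibsp (-1.67) fell, the only members of the adhesion, osteoclast, smooth muscle and osteoblast lists past the test, named after their values were seen, as is Ldb2 (3.79), whose probe set of highest mean did not pass.

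In this contrast 199 probe sets passed, 152 higher and 47 lower in Crebbp+/-. They shared 122 with those called against wild type, all in the same direction, 103 higher and 19 lower, where independent lists would share 7.63 and 0.544. Both contrasts use the same Crebbp+/- arrays, and lists of equal length drawn from simulated unchanged groups that share them had 43.2 and 7.89 in common, or 39.2 and 7.31 with same-numbered arrays correlated as observed. These values leave out the effects, so the excess is not read as a shared effect. The count was 9, 38, 132 and 374 without Crebbp+/- 1, 2, 3 and 4, and 2, 121, 322 and 59 without Ep300+/- 1, 2, 3 and 4, and 760 with the replicate block. Of the 12 genes of largest change and Crebbp, 12, 12, 13 and 12 stayed past the threshold without wild-type 1, 2, 3 and 4, 3, 4, 8 and 13 without Crebbp+/- 1, 2, 3 and 4, and 1, 10, 12 and 5 without Ep300+/- 1, 2, 3 and 4. It was 51 in a fit of these 2 genotypes alone and 0 with the Y-linked covariate.

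Across probe sets, which are not independent, the fold changes of the 2 heterozygotes against wild type correlated with r = 0.416, while unchanged groups simulated against the same wild-type arrays gave 0.504. The covariance was 0.173 against a simulated 0.127. Those simulations had no pairing by replicate number, and with same-numbered arrays correlated as observed they gave 0.444 and 0.0591. With different wild-type pairs for each heterozygote, r over the 6 ways of splitting them lay between -0.16 and 0.348. No probe set was called in both contrasts, as limma called 0 in Ep300+/- (126 at an unadjusted p under 0.05).

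**Figure D2:**
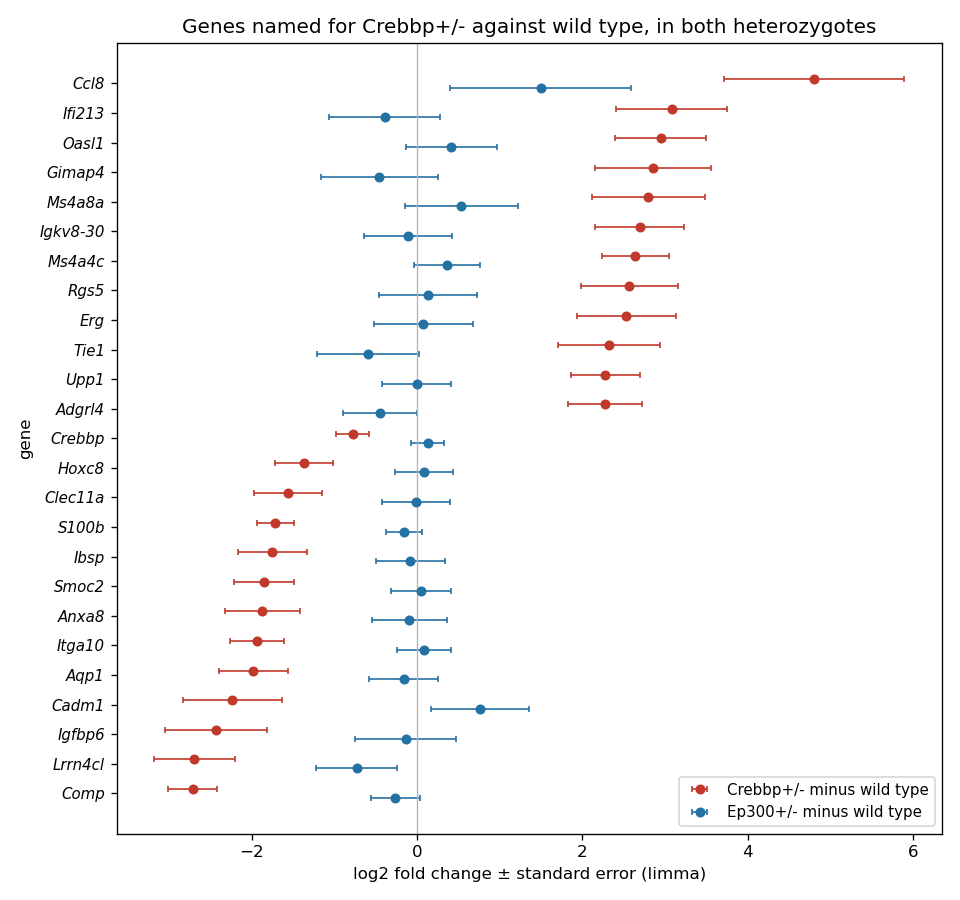
Log2 fold change against wild type (horizontal axis) with limma's standard error, for Crebbp and the 24 genes named for Crebbp+/- (vertical axis), in Crebbp+/- and in Ep300+/- (n = 4 arrays per genotype). Ccl8 stands at 4.81 and Comp at -2.71 in Crebbp+/-, and none of the 25 genes passed in Ep300+/-.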

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

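The tests on endothelial cells, other cell types, donor sex, spike-in controls and interferon with endothelial signal were chosen after the values had been seen.

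Among 144 groups of 4 arrays examined, 18 held 1 array far from the other 3, where independent groups would give about 7.2 by chance. These groups share the same 12 arrays and hold genes that move together, so the excess is not a test. Low values close together can also make 1 array stand out, as in wild type for Ccl8 (3.66 to 3.68) and Oasl1 (4.12 to 4.13). Crebbp+/- 4 was that array for Ms4a8a (5.41), Rgs5 (11.69), Erg (4.91), Cldn5 (6.22), Lrrn4cl (6.62), Tspan32 (7.22) and the sterol list mean (-0.025). Wild-type 1 was highest for Ccl8 (6.42), Oasl1 (4.67), Gimap4 (6.75) and Tie1 (7.10), and wild-type 3 for the NF-kB mean (-0.27). Ep300+/- 3 stood apart for Oasl1 (6.51), Upp1 (5.27) and Itga10 (6.51), Ep300+/- 4 for Rgs5 (9.09) and the Wnt mean (-1.04), and Ep300+/- 2 for Rnf144b (7.30).

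The endothelial list was higher in Crebbp+/-, least so on Crebbp+/- 4. A lower share of another cell type would raise all other markers alike, but the endothelial median fold change exceeded that of a pool of 27 markers of other types by 1.66. The SE set against it, 0.39, came from a related measure, the gap between the 2 medians on each array. The pool may itself hold the type that was lost, whose markers would fall. By type, from few markers each, the medians were 0.51 (macrophage), 0.28 (smooth muscle), -0.012 (osteoclast), -0.39 (adipocyte) and -1.03 (osteoblast). More endothelial cells in the culture is a candidate explanation. The members' deviations had a median pairwise correlation of 0.905, against a 95th percentile of 0.378 in random gene sets. The interferon list, which is not a set of cell type markers, had 0.763. A high value is thus not particular to cell type markers and does not favour more cells. No measured member is in another fixed list, and the members Plvap and Egfl7 stood at 10.34 and 10.08 in Crebbp+/- against 9.34 and 8.35 in wild type. That test cannot separate more cells from more of each transcript per cell. Donor sex stays open, since of the arrays with the Y-linked transcript Crebbp+/- 2 lay above the highest wild-type mean by 1.17 and Crebbp+/- 4 below it (-0.29).

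The interferon list was higher on all 4 Crebbp+/- arrays, also on Crebbp+/- 4 (0.60), whose endothelial mean (0.047) lay below that of wild-type 1 (0.33, interferon -0.63). Labelled RNA amount is argued against, since the list's mean fold change with the spike-in covariate was 1.0 times that without it (1.501, SE 0.36). Donor sex is too, because Crebbp+/- 2 and 4 both lay above every wild-type mean, the nearer by 0.93, with a wild-type range of 0.40. Whether the signal comes with endothelial cells cannot be told apart at this number of arrays, with r = 0.529 between the list means' deviations (permutation p = 0.0780, Spearman rho 0.531, permutation p = 0.0810). Without Crebbp+/- 4 and wild-type 1, whose endothelial means lay farthest from those of their groups, r was 0.658. Ep300+/- 3 stood at -0.47 in the endothelial and 0.54 in the interferon list. A direct effect of Crebbp dose was not tested and stays open.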

How the results depend on the processing

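The spike-in and Y-linked covariates, leaving out Crebbp+/- 3 with Ep300+/- 3, and the block with an estimated correlation were chosen after the data were seen. Counts of calls are given for Crebbp+/- against wild type, Ep300+/- against wild type and Crebbp+/- against Ep300+/-, with 192, 0 and 199 as reported. Quantile normalization, median centring, eBayes with trend and robust and the fold minimum kept each within 1.5 times, and the filter on low values removed 0 probe sets, so it tested nothing. Leaving out 1 array gave 5 to 383, 0 to 1 and 2 to 374. The replicate block gave 812, 1 and 760. For Ep300+/- and wild type not every same-numbered pair was above the bound of 0.1, with r from 0.0593 to 0.683. Of 8 arrays, 4 correlated best with their own number, against 6 of 8 in each of the other 2 comparisons. The mean r was 0.405, against 0.402 between the heterozygotes, so the bound does not show these arrays to be unpaired. Array weights, which put 10.3 on Crebbp+/- 1, gave 1425, 18 and 1533. The Y-linked covariate gave 3, 0 and 0, and it rests the Crebbp+/- mean on Crebbp+/- 2 and 4. Between the heterozygotes, fitting these 2 genotypes alone gave 51, the spike-in covariate 329, and leaving out Crebbp+/- 3 with Ep300+/- 3 122. Where not shown by construction, the cause was not tested.

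The interferon, endothelial and sterol calls in Crebbp+/- held without any 1 array, with the block, with fry and under quantile normalization. They did not with an estimated correlation (adjusted p = 0.538 each), nor with that and the block (0.799 each). The 6 Ep300+/- lists gave 0.628 or, for endothelial markers, 0.783 with an estimated correlation, 0.654 or 0.767 by fry, and 0.416 or 0.776 with the block and an estimated correlation. Adjusted p for these ranged without 1 array from 0.00932 to 0.0810 (matrix), 7.13e-06 to 0.0810 (cAMP), 0.0250 to 0.329 (Wnt) and 4.51e-04 to 0.185 (endothelial). With the spike-in covariate it was 0.175 for matrix and 0.0523 for Wnt, and 0.0583 for Wnt on the mean of a gene's probe sets. The block alone changed no list call. Of genes not past the test in Crebbp+/- against wild type, Cidec (0.24) and Scd1 (0.0062) turned positive with array weights and Cd14 (-0.39) negative with the Y-linked covariate.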

Other observations

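The tests on chromosome 1 and the split of the Ep300+/- arrays were chosen after the values had been seen. The other splits and the test of genes near Crebbp had their bounds written before their own results, though after the calls had been counted.

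Some genes outside the naming rule, chosen after their values were seen, also differed. A probe set with no gene name here had a mean of 7.49 ± 1.02 in Crebbp+/- (SD, n = 4), 2.83 ± 0.07 in wild type and 3.25 ± 1.03 in Ep300+/- (limma adjusted p = 0.00155 against wild type), low values in the latter 2 that leave the size of the change uncertain. Gimap6, a GTPase of the same family as Gimap4, was higher in Crebbp+/- than in wild type by 2.08 (limma adjusted p = 0.0293).

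Chance was tested by regrouping the 8 arrays of each comparison in all 35 ways. For Crebbp+/- against wild type 1 split, the real one, gave 192 calls or more, and the highest other gave 89. That would exclude chance only for unpaired arrays. The replicate numbers were taken to pair these arrays, so chance is not excluded. For Crebbp+/- against Ep300+/- 2 of 35 splits gave as many as 199, so chance is not excluded: exchanging Crebbp+/- 4 with Ep300+/- 3 gave 630, which points to a structure of the samples. That split puts both arrays numbered 3 on one side and both numbered 4 on the other. Other splits that do the same gave 0 or 5 calls, so this placement of the numbers does not by itself account for the 630. The structure was not identified, and what the numbers share is not known. Paired, only 8 splits part all 4 pairs, too few for chance to be excluded, and the highest other gave 0 in both comparisons, with and without the block, against 812 and 760 for the real splits with it. For Ep300+/- against wild type all 35 gave as many as the real 0, and the highest other gave 0.

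Genes that differ from wild type in the mean of both heterozygotes may partly reflect a chromosome 1 segment that differs between the wild-type mice and both heterozygous lines. Only the share of genes on the whole chromosome was tested, not whether they lie together in a segment. Of the 50 genes of smallest p for the mean of both heterozygotes against wild type, 10 lie on chromosome 1, among them Stk25, Klf7, Shisa4, Nav1 and Ctse, against 140 of 1972 overall. Not all 10 shifted alike, as F11r and Rgs4 had log2 fold changes of 1.36 and 1.72 in Crebbp+/- but 0.28 and 0.26 in Ep300+/-. The one-sided Fisher exact p times the 20 chromosomes was 0.0413, but 0.132 with 25 genes and 1 with 100, and chromosome 1 was singled out from the same list, so this remains a weak hypothesis. Between the heterozygotes, which leaves out wild type, 1 of 50 lay there (Fisher exact p = 0.976), and so few genes cannot tell whether chromosome 1 genes vary more in general. Only 3 probe sets passed for the mean of both, and for Btg2, chosen after its values were seen, 1 probe set was higher by 4.76 while the other had log2 fold changes of 0.48 and 0.74 in Crebbp+/- and Ep300+/-.

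A passenger region around the targeted gene would make its neighbours change. Of the 11 nearest measured genes 0 were called against 130 of 1960 others (one-sided Fisher exact p = 1). At that rate only 0.730 calls would be found among them, so the bound set for it was too weak and the test decides nothing.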
